A study of Mus musculus with 18 samples.

How the data were processed

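The series holds RNA sequencing of kidney from ICR mice aged 10 weeks, in 18 samples that the labels put into 6 groups of 3 (control, AOS, HS, HS_AOS, HS_AOS_FMT and HS_control_FMT). Per the submitters' processing notes the tool was Bowtie 0.12.2 and the genome build mm10. The program that made the values per gene, its annotation, the strandedness of the libraries and any filter are not given in the sources used here. The deposited table gives 1 value per gene symbol and sample in FPKM, made by the authors before deposit and rounded to 2 decimals, with 19545 genes and no read counts. That unit was read from the values: multiplied by transcript length they summed to nearly the same total in every sample (coefficient of variation 0.93%, against 4.29% for the plain sum). No counts or library totals are given, so no test on counts was run. Depth was estimated from the 890 short genes with 1 transcript, whose low values times length clustered at steps of 0.085 to 0.115, which would stand for 8.7 to 11.8 M reads if 1 step is 1 read. The steps were read on a coarse grid and held a minority of these genes, so whole reads were not recovered. A test on counts had been planned first and limma on log values as the fallback for normalized values, so the fallback was used.

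Groups, comparisons, tests, gene lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined. Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 of the 18 samples were tested, which kept 12385 genes and left out 7160. A model with 1 mean per group was fitted over all 18 samples in limma 3.58.1 (R 4.3.3) with the trend and robust options, on 12 residual degrees of freedom. P-values were adjusted over the genes of each comparison by the method of Benjamini and Hochberg, with a threshold of 0.05, and all p-values in this text are limma's. The main comparisons were HS vs control, HS_AOS vs HS, HS_AOS_FMT vs HS, HS_control_FMT vs HS, HS_AOS_FMT vs HS_control_FMT and AOS vs control. The difference of the AOS effect between HS and control and the 3 treated HS groups against control were tested as well.

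Of 43 fixed gene lists, 39 with at least 5 tested members were tested with limma's camera at a correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with the correlation estimated from the data, and limma's fry, were run beside it. Members of a list were counted when they passed over all genes, and again when adjusted over the list alone. Named genes were, per main comparison, the 10 raised and the 10 lowered with the largest change among those that passed, whose 3 values in 1 group all lay above the 3 of the other, with a mean of at least 2 FPKM in the higher group. Symbols of predicted genes and pseudogenes were left out. The 4 members with the smallest p in each list that passed were named too, and any other gene is marked as chosen after its values were seen. Gene positions are from the RefSeq table of GRCm38.

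Called genes shared between comparisons with the same HS samples were set beside 100 simulations in which no group differed. Pearson correlations between libraries were taken over the tested genes. The Y-linked gene Ddx3y lay between 7.32 and 15.7 FPKM in all 18 libraries, so the groups were not seen to differ in sex.

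The test was tried on simulated data modelled on HS_AOS vs HS, with 200 changed genes among 12385. The changed genes were drawn from those with a mean log2 level of at least 2. The noise was independent between genes, without structure shared within a library. It recovered 93% of those changed by 2-fold and 100% of those changed by 4-fold, with 6 false calls. With a trend in GC content of opposite slope added to the 2 groups, 9660 false calls were made, and removing the trend brought them back to 6. The added trend was linear, of a fixed size and the same in every library of a group. In the data the rank correlation of a library's deviations with GC content was 0.11, -0.239 and -0.592 in HS_AOS 1, 2 and 3. The recovery therefore does not measure how well the removal works on these libraries.

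The alternatives were the replicate number as a block, quantile normalization, limma without its trend option, limma with array weights, no filter, at least 5 FPKM in 3 samples, the compared groups alone in the fit, a pseudocount of 0.1, a log2 fold change of at least 1, and each library left out in turn. Where that left 2 samples in a group, the pooled fit assumes that they vary like the other groups. After the data had been seen, 3 more were added. These removed each library's trend with GC content and log2 transcript length by natural splines with 4 degrees of freedom each, over the 12254 tested genes with a GENCODE transcript (98.9%), left out the 3 most adrenal-rich libraries (control 3, HS 3 and HS_AOS_FMT 2), or left control 3 out of the fit.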

Results

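Kidney RNA was sequenced from ICR mice aged 10 weeks, in 18 samples that formed 6 groups of 3. The control group carries no treatment in its labels, and the AOS group was given AOS, a compound the labels do not spell out, at 10 mg/kg. The HS group had a high fat diet and STZ, that is streptozotocin, a toxin of pancreatic beta cells used to raise blood glucose. HS_AOS combined HS with AOS. HS_AOS_FMT and HS_control_FMT were HS groups with an FMT (faecal microbiota transplantation) labelled by AOS at 10 mg/kg or by control. The labels do not say that the 3 samples of a group came from separate mice, so the p-values measure only the spread between these samples. Levels are FPKM given as the mean ± SD of 3 samples, and fold changes are on the scale of log2(FPKM + 1), which understates changes of genes at low levels. The deposited table lists between 15773 and 17270 of its 19545 genes above 0 in a library. It holds no read counts, and low values of short genes clustered at steps that would put the libraries at roughly 8.7 to 11.8 M reads, if 1 step is 1 read.

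Some libraries carried transcripts of neighbouring or unrelated tissues. The adrenal markers Cyp11b1, the last enzyme of corticosterone synthesis, and Chga, a protein of chromaffin granules, were chosen from the adrenal list after their values were seen, as were Kap and Havcr1 below. Cyp11b1 was at 118 FPKM in control 3, 38.3 in HS 3, 38.2 in HS_AOS_FMT 2 and 6.11 in HS_AOS_FMT 3, and at 0.59 or less in the other libraries. Chga was at 7.31, 47.7, 24.5 and 4.83 FPKM in the same libraries and at 0.54 or less elsewhere. Control 3 also stood apart as a whole: its correlations with the other libraries, across genes, lay between 0.947 and 0.965. Its level of Kap, an androgen-regulated transcript of the proximal tubule, was 15798 FPKM, against 66020 or more in the rest. Havcr1, the kidney injury molecule, was at 19.4 FPKM in control 3 and at 5.3 or less elsewhere.

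**Figure D1:**
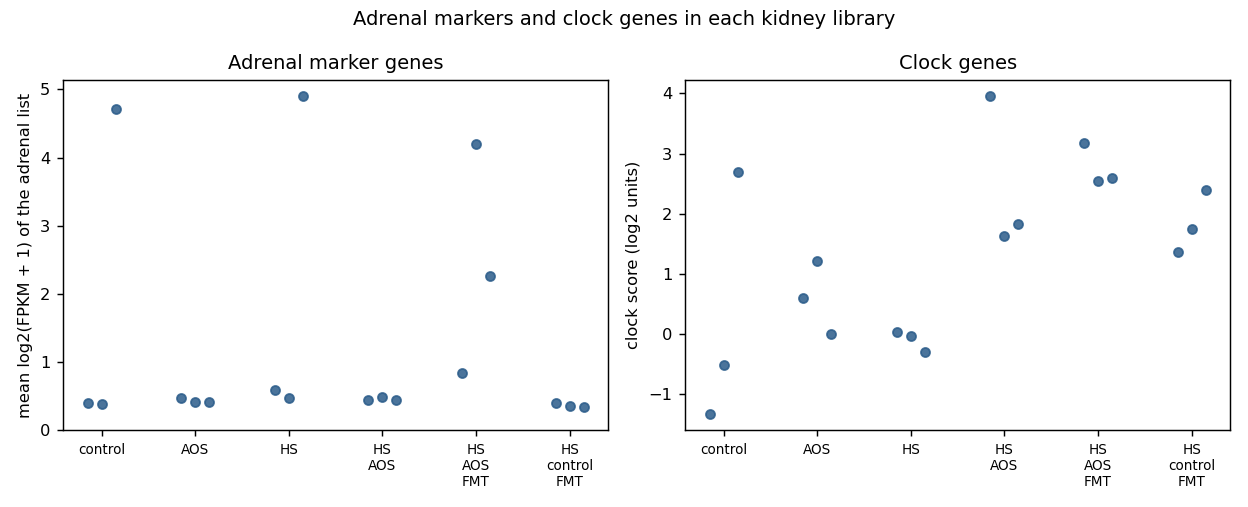
Each point is 1 kidney library, placed by group, with the mean log2(FPKM + 1) of the adrenal marker list on the left and a clock score in log2 units on the right (the mean of Dbp, Per2, Per3, Ciart, Tef and Nr1d2 minus that of Arntl, Npas2, Nfil3 and Clock). Control 3, HS 3, HS_AOS_FMT 2 and HS_AOS_FMT 3 had adrenal means of 4.71, 4.91, 4.2 and 2.26, and the clock scores of the 3 HS libraries lay between -0.296 and 0.037.

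The first question was what the high fat diet and STZ changed in the kidney. Genes of fatty acid and triglyceride synthesis fell as a list in HS against control, with a median log2 change of -0.34 over 19 members (adjusted p = 0.000327, and adjusted p = 0.439 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, was at 12.6 ± 9.84 FPKM in HS and 55.3 ± 27.2 in control (log2 -2.15, adjusted p = 0.146). Fasn, the fatty acid synthase, was at 6.46 ± 2.67 FPKM in HS and 19.2 ± 10.9 in control (log2 -1.31, adjusted p = 0.508). With limma 0 of the 19 members passed over all genes, 3 were lower when adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. The cholesterol synthesis list also fell (20 members, median log2 -0.29, adjusted p = 7.29e-05, and adjusted p = 0.439 with an estimated correlation). Markers of the thick ascending limb fell as a list (12 members, median log2 -0.45, adjusted p = 1.39e-05, and adjusted p = 0.439 with an estimated correlation). The median was -0.14 (adjusted p = 0.00583) without the 3 most adrenal-rich libraries (control 3, HS 3 and HS_AOS_FMT 2). Among these markers Egf, which encodes epidermal growth factor, was at 177 ± 16.6 FPKM in HS and 284 ± 37.6 in control (adjusted p = 0.146). Umod, which encodes uromodulin, was at 525 ± 99.8 and 874 ± 171 FPKM (adjusted p = 0.704). Markers of other cells moved too. The lists of the distal convoluted and connecting tubule (adjusted p = 0.00851), of principal cells (0.00942) and of intercalated cells (0.0192) fell, and that of the endothelium rose (0.0195), with adjusted p = 0.846, 0.846, 0.846 and 0.899 with an estimated correlation. Without the 3 adrenal-rich libraries the first 3 were not called (adjusted p = 0.977, 0.442 and 0.977), nor were they without control 3 (0.273, 0.273 and 0.395), and the endothelial list was not called without control 1 (adjusted p = 1), HS 2 (0.125) or HS 3 (0.0989). The list of erythroid markers rose too, with all 9 members higher (adjusted p = 0.00139). It was not called without control 3 (adjusted p = 0.505), without the 3 adrenal-rich libraries (0.977) or with an estimated correlation. The heat shock list rose with a median log2 change of 0.36 over 16 members (adjusted p = 9.91e-06, and adjusted p = 0.466 with an estimated correlation), a call that ended without control 3 (adjusted p = 0.26) or without the 3 adrenal-rich libraries (adjusted p = 0.977).

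Among the genes that passed, those with the largest changes between HS and control were germ cell transcripts found in the control libraries. Prm1 and Prm2 encode protamines, which pack sperm DNA, and Tnp1 and Tnp2 encode the transition proteins that precede them. In controls 1, 2 and 3, Prm1 was at 9.07, 9.44 and 14.5 FPKM, Tnp2 at 7.15, 7.33 and 11.1, Prm2 at 4.99, 5.7 and 6.86, and Tnp1 at 5.53, 3.6 and 4.63. All 4 genes were listed at 0 in the 3 HS and the 3 AOS libraries. Prm1 (chromosome 16, 10796332 to 10796823, GRCm38) and Prm2 (chromosome 16, 10791377 to 10792105) are neighbours, and Prm1 had an adjusted p of 1.02e-09. Of the 16 members of the testis list 8 passed the filter and were tested, and germ cell genes near 0 elsewhere passed it only through the 3 controls. Of these 8 members 5 fell over all genes and 5 when adjusted over the list alone. The list passed with either correlation (adjusted p = 5.24e-26, and adjusted p = 0.000269 with an estimated correlation). Since the filter favoured members high in the controls, these p-values add no independent support. In all, 8 of 12385 genes passed limma, 1 higher and 7 lower, and 821 had an unadjusted p under 0.05. The gene that rose was Gm20594, at 1193 ± 182 FPKM in HS and 514 ± 105 in control, named after its values were seen. The groups did not overlap for 8.53% of the genes, where chance gives 10%. Of 39 lists, 15 passed, 6 up and 9 down, and 1 of them, the testis list, held with an estimated correlation. The count of genes was 0 without control 1 or control 2, where germ cell genes above 1 FPKM in the controls alone missed the minimum of 3 samples. Gm20594 was not called there either, for a reason that was not tested, nor with the replicate number as a block, which gave 0 higher and 7 lower. The count was 4 without the 3 adrenal-rich libraries, control 3 among them, where the same germ cell genes missed the minimum. Of these 4 genes 0 were among the 8. The count of lists was 9 without control 1.

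**Figure D2:**
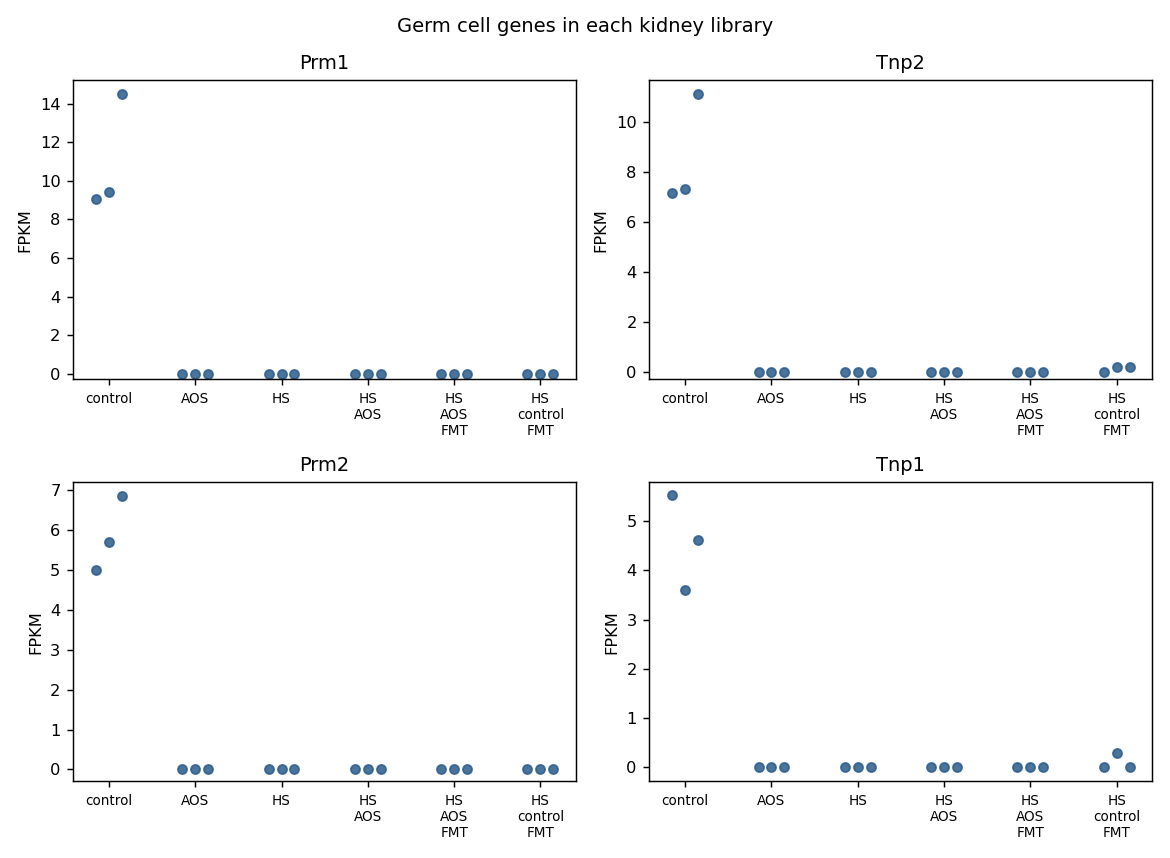
Each point is the FPKM of a germ cell gene in 1 kidney library, placed by group, for Prm1, Tnp2, Prm2 and Tnp1. Prm1 was at 9.07, 9.44 and 14.5 FPKM in the 3 control libraries and at or near 0 in the other 15.

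Leaving out control 3 brought lipid genes past the threshold. Without it, Fasn fell by 1.87 on the log2 scale in HS (adjusted p = 0.0402), and Acaca, which encodes acetyl-CoA carboxylase, fell by 0.97 (adjusted p = 0.0436). Fasn was at 28.1 FPKM in control 1, 22.3 in control 2 and 7 in control 3. Gdf15, a cytokine induced by cell stress, rose by 1.81 on the log2 scale (adjusted p = 0.015), from 4.31 and 4.28 FPKM in controls 1 and 2 to 17.7 ± 2.88 in HS. Its level in control 3 was 28.2 FPKM. These genes were named after their values were seen, among 6 that passed without control 3, where the spread of the 2 controls left is pooled with that of the other groups.

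To ask what AOS changed in HS kidneys, HS_AOS was compared with HS. Ppara, the nuclear receptor that drives fatty acid oxidation, rose from 11.8 ± 1.63 to 21.5 ± 4.02 FPKM (log2 0.80, SE 0.142, adjusted p = 0.0168). Mttp, which loads triglyceride onto lipoproteins, rose from 5.42 ± 0.766 to 9.98 ± 1.4 FPKM, and Hlf, a transcription factor under the clock, from 21.2 ± 2.53 to 35.7 ± 7.17. Hspb1, a small heat shock protein (chromosome 5, 135887919 to 135889563), fell from 83.4 ± 50.1 to 16.1 ± 2.33 FPKM (log2 -2.07, SE 0.438, adjusted p = 0.0331). Nfil3, a transcriptional repressor under the clock, fell from 11.2 ± 5.48 to 2.13 ± 0.362 FPKM. Hmox1, the heme oxygenase induced by oxidative stress, fell from 59.8 ± 5.95 to 38 ± 9.2 FPKM (log2 -0.66, adjusted p = 0.0435). Akr1e1 (log2 0.95), Slc35f3 (0.86) and Tnfrsf21 (0.78) also rose. Cnbd2 (log2 -1.06), Hist2h2aa1 (-1.05) and Defb29 (-0.97) fell.

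By list, the heat shock proteins fell in HS_AOS against HS, with a median log2 change of -0.55 over 16 members (adjusted p = 7.18e-05, and adjusted p = 0.904 with an estimated correlation). Of these, Hspb1 and Hspe1 fell over all genes, the latter from 352 ± 35.5 to 248 ± 21 FPKM, and 5 fell when adjusted over the list alone. The call of this list held without any 1 of the 6 libraries. Immediate early genes fell beside it, with 19 of 21 members lower (adjusted p = 0.0195), though not without HS_AOS 2 (adjusted p = 0.054) or with an estimated correlation. Fatty acid oxidation genes rose (33 members, median log2 0.24, adjusted p = 0.0195, and adjusted p = 0.904 with an estimated correlation), with Ppara as the member that passed over all genes and over the list alone. This call ended without HS 2 (adjusted p = 0.393), HS 3 (0.0509), HS_AOS 1 (0.112) or HS_AOS 2 (0.0737). Proximal tubule transporters rose (24 members, median log2 0.22, adjusted p = 0.0286, and adjusted p = 0.559 with an estimated correlation). Slc6a19, a neutral amino acid transporter, was at 126 ± 26.4 FPKM in HS_AOS and 59.9 ± 4.97 in HS (adjusted p = 0.0778). With limma 0 of these transporters passed over all genes, 4 were higher when adjusted over the list alone, and 7 were higher and 2 lower at an unadjusted p under 0.05. That list was not called without HS 3 (adjusted p = 0.094), HS_AOS 1 (0.0648) or HS_AOS 2 (0.0966). Markers of the thick ascending limb fell in the same comparison (12 members, median log2 -0.40, adjusted p = 0.024, and adjusted p = 0.904 with an estimated correlation), though not without HS 2 (adjusted p = 0.106), HS_AOS 1 (0.0648) or HS_AOS 2 (0.0799). The adrenal list fell (14 members, adjusted p = 0.0201, and adjusted p = 0.904 with an estimated correlation), and it did not without HS 3 (adjusted p = 0.843), the library with the adrenal transcripts, or without HS_AOS 1 (0.0806) or HS_AOS 2 (0.054).

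In HS_AOS against HS 285 of 12385 genes passed limma, 136 higher and 149 lower, and 2511 had an unadjusted p under 0.05. The groups did not overlap for 24.7% of the genes, where chance gives 10%. Of 39 lists 8 passed, and 0 held with an estimated correlation. The number of lists was 3 without HS 3 or HS_AOS 1 and 1 without HS_AOS 2. Genes that rose had a median GC content of 44.3% and those that fell 55.8%, and with the trend in GC content and transcript length removed 19 genes were called, 15 higher and 4 lower, of which 14 were among the 285. After quantile normalization 477 passed, 279 higher and 198 lower, so the side with more genes turned. The count was 541 without HS 1, 0 without HS 2 or HS 3, 789 without HS_AOS 1, 63 without HS_AOS 2, 17 without HS_AOS 3, 0 without the 3 adrenal-rich libraries and 828 with control 3 left out of the fit, 436 higher and 392 lower.

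Whether the transfer labelled AOS changed HS kidneys was asked by comparing HS_AOS_FMT with HS. Fos, an immediate early transcription factor, rose from 0.987 ± 0.101 to 6.91 ± 3.69 FPKM (log2 1.88, SE 0.401, adjusted p = 0.0421). Tnfrsf21, a death receptor of the tumour necrosis factor family, rose from 30.4 ± 4.58 to 63.9 ± 6.52 FPKM, and Upp2, a uridine phosphorylase, from 6.67 ± 2.79 to 16.3 ± 2.31. Rnase4, a secreted ribonuclease, rose from 27.7 ± 11.5 to 83.5 ± 24.7 FPKM. Hmox1 fell from 59.8 ± 5.95 to 33.4 ± 2.46 FPKM (chromosome 8, 75093618 to 75100593; log2 -0.82, SE 0.159, adjusted p = 0.0369), a level next to the 37.2 ± 3.05 of control. It was not among the 8 genes called in HS vs control. Ypel2 (log2 -1.08), Palm3 (-0.98), Banp (-0.97) and Bcl7c (-0.81) also fell.

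The clock list rose in HS_AOS_FMT against HS, with a median log2 change of 0.63 over 20 members (adjusted p = 0.00785, and adjusted p = 0.688 with an estimated correlation), and this call held without any 1 of the 6 libraries. Its members moved both ways: Hlf rose over all genes (log2 0.74), while 9 were higher and 3 lower when adjusted over the list alone. Per3, a period gene of the clock, was at 7.49 ± 0.825 FPKM in HS_AOS_FMT and 1.82 ± 0.47 in HS (adjusted p = 0.0678), and Tef, an output gene of the clock, at 107 ± 8.66 and 49.6 ± 5.48 (adjusted p = 0.0612). Immediate early genes rose (21 members, median log2 0.48, adjusted p = 0.0204, and adjusted p = 0.876 with an estimated correlation), with Fos passing over all genes and 5 higher when adjusted over the list alone. This call ended without HS_AOS_FMT 3 (adjusted p = 0.115). Jun was at 47 ± 9.25 FPKM in HS_AOS_FMT and 20.7 ± 6.41 in HS (adjusted p = 0.0686). The glycolysis list fell (15 members, median log2 -0.21, adjusted p = 0.00785, and adjusted p = 0.688 with an estimated correlation). With limma 0 of its members passed over all genes, 2 were lower when adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. It was not called after quantile normalization (adjusted p = 0.206) or with the trend in GC content and length removed (adjusted p = 0.0932). Markers of cell types moved in the same comparison. The lists of the endothelium (adjusted p = 0.0204), the distal convoluted and connecting tubule (0.0205), erythroid cells (0.0205), liver (0.0208), macrophages and monocytes (0.0332) and principal cells (0.0427) fell and that of proximal tubule transport rose (0.0332). With an estimated correlation these had adjusted p = 0.876, 0.876, 0.688, 0.876, 0.876, 0.876 and 0.688. Each of these 7 calls ended when some single HS library was left out, and when some single HS_AOS_FMT library was.

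In HS_AOS_FMT against HS 121 genes passed limma, 55 higher and 66 lower, and 2241 had an unadjusted p under 0.05. The groups did not overlap for 29.5% of the genes, where chance gives 10%. Of 39 lists 14 passed, and 0 held with an estimated correlation. The count of lists was 9 without HS 3, HS_AOS_FMT 1 or HS_AOS_FMT 2. Genes that rose had a median GC content of 45.4% and those that fell 56.5%, and with the trend in GC content and length removed 28 genes were called, 19 higher and 9 lower, of which 16 were among the 121. After quantile normalization 176 passed, 100 higher and 76 lower. The count was 2 without HS 2, 69 without HS_AOS_FMT 1, 0 without HS 3, HS_AOS_FMT 2 or HS_AOS_FMT 3, 1 without the 3 adrenal-rich libraries, which was not among the 121, and 619 with control 3 left out of the fit.

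The transfer labelled control was examined by comparing HS_control_FMT with HS, and genes of protein folding and stress were among those that rose. Creld2, a chaperone of the endoplasmic reticulum (chromosome 15, 88819646 to 88826681), rose from 28.1 ± 6.84 to 81.9 ± 9.5 FPKM (log2 1.53, SE 0.197, adjusted p = 0.00325). Herpud1, a part of the degradation of misfolded proteins there, rose from 136 ± 24.1 to 385 ± 36.7 FPKM. Hmox1 rose from 59.8 ± 5.95 to 162 ± 32.4 FPKM (log2 1.41, SE 0.159, adjusted p = 0.00206). Sdf2l1, Chac1 and Maff rose by 1.31, 1.35 and 1.79 on the log2 scale. Tmem252 rose from 64.2 ± 9.1 to 240 ± 38.4 FPKM (log2 1.89, adjusted p = 0.00325). Zbtb16, a transcription factor induced by glucocorticoids, rose from 0.297 ± 0.0493 to 3.22 ± 1.33 FPKM. Pde9a, a phosphodiesterase of cyclic GMP, fell from 21.8 ± 2.28 to 11.3 ± 0.749 FPKM, and Fpgs, the folylpolyglutamate synthase, from 30.5 ± 3.83 to 16.2 ± 0.717.

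The list of endoplasmic reticulum stress and amino acid response genes rose in HS_control_FMT against HS, with a median log2 change of 0.48 over 26 members (adjusted p = 1.58e-18, and adjusted p = 0.0269 with an estimated correlation). Of these 9 rose over all genes, 17 did not pass, and 15 rose when adjusted over the list alone. Dnajb9 rose from 31.3 ± 2.09 to 72.7 ± 5 FPKM and Pdia4 from 35.7 ± 5.96 to 66.1 ± 5.18. The heat shock proteins rose with a median log2 change of 0.99 over 16 members (adjusted p = 3.48e-15, and adjusted p = 0.18 with an estimated correlation). Of these 2 rose over all genes, Hspa8 from 1531 ± 385 to 2976 ± 140 FPKM and Hspa4l from 10.1 ± 2.15 to 21.1 ± 2.78, and 13 rose when adjusted over the list alone. Hsph1 was at 190 ± 17.5 FPKM in HS_control_FMT and 62.9 ± 30 in HS (adjusted p = 0.073). The clock list rose (20 members, median log2 0.64, adjusted p = 8.72e-07, and adjusted p = 0.264 with an estimated correlation). With limma 0 of its members passed over all genes, 7 were higher when adjusted over the list alone, and 10 were higher and 1 lower at an unadjusted p under 0.05. Per2 was at 14.7 ± 2.8 FPKM in HS_control_FMT and 4.03 ± 1.64 in HS (adjusted p = 0.0925). Cell cycle genes fell as a list (20 members, median log2 -0.48, adjusted p = 0.000204, and adjusted p = 0.877 with an estimated correlation). All 20 had lower means on the log2 scale, 10 of them at an unadjusted p under 0.05, while 0 passed limma over all genes or adjusted over the list alone. Mcm2, a part of the replicative helicase, was at 2.75 ± 0.741 FPKM in HS_control_FMT and 5.23 ± 0.864 in HS (adjusted p = 0.2). These 4 lists were called without any 1 of the 6 libraries too. So were the immediate early genes, which rose with 16 of 21 members higher (adjusted p = 0.000143), though not with an estimated correlation. Markers of the endothelium fell (adjusted p = 0.0475) and those of adipose tissue rose (adjusted p = 0.000896), both with adjusted p = 0.877 with an estimated correlation. The first was not called without HS 2 (adjusted p = 0.246), HS 3 (0.147) or HS_control_FMT 3 (0.469), and the second without HS 2 (0.373) or HS_control_FMT 1 (0.105).

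In HS_control_FMT against HS 93 genes passed limma, 57 higher and 36 lower, and 1882 had an unadjusted p under 0.05. The groups did not overlap for 25.3% of the genes, where chance gives 10%. Of 39 lists 11 passed, and the endoplasmic reticulum stress list was the 1 that held with an estimated correlation. The count was 16 without HS 1, 25 without HS 2, 30 without HS 3, 18 without HS_control_FMT 1 or HS_control_FMT 2, 45 without HS_control_FMT 3 and 350 with control 3 left out of the fit, where 141 were higher and 209 lower, so the side with more genes turned. Removing the trend with GC content and length gave 178 genes, 122 higher and 56 lower, and quantile normalization gave 139, 105 higher and 34 lower.

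**Figure D3:**
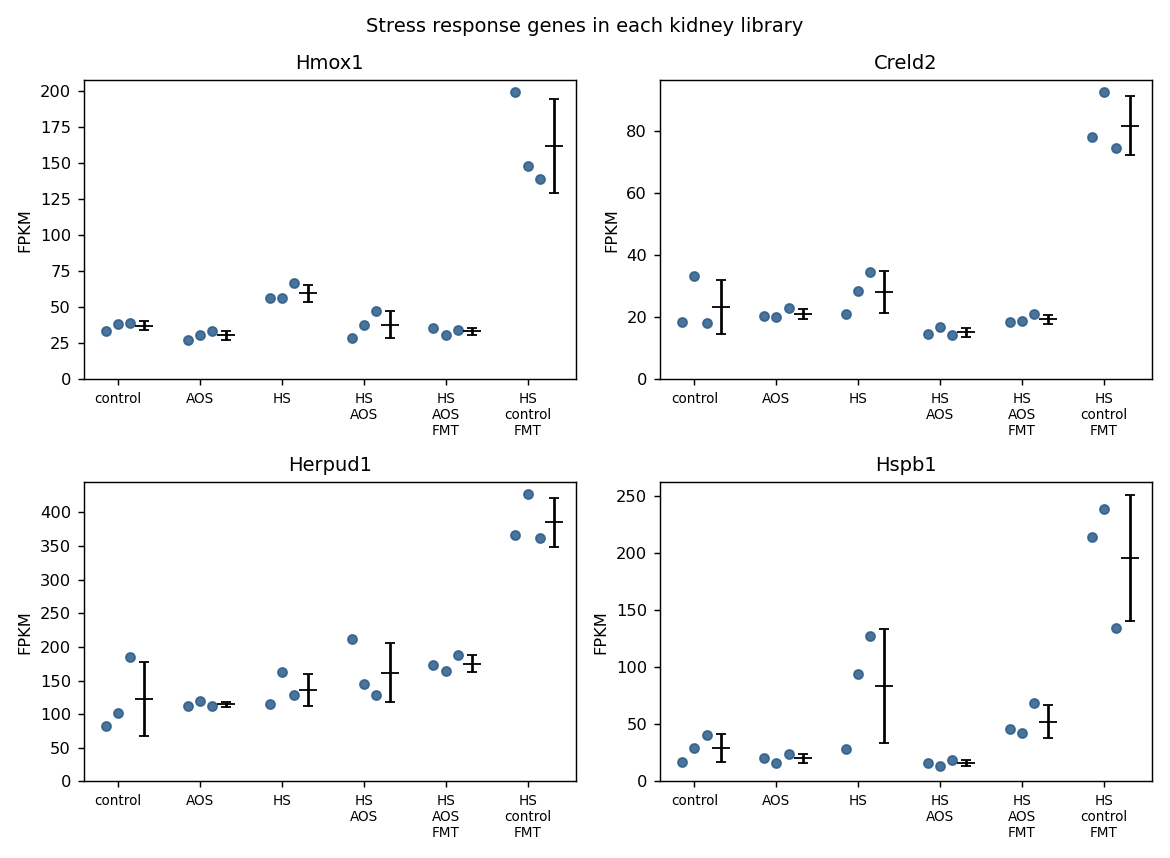
Each point is the FPKM of Hmox1, Creld2, Herpud1 or Hspb1 in 1 kidney library, placed by group, with the mean and SD of 3 libraries as a bar beside them. Hmox1 lay between 139 and 199 FPKM in the 3 HS_control_FMT libraries and between 30.6 and 35.3 in the 3 HS_AOS_FMT libraries.

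The series title names the transfer from AOS as its subject, and HS_AOS_FMT against HS_control_FMT sets the 2 transfers side by side. Hmox1 was lower in HS_AOS_FMT, at 33.4 ± 2.46 against 162 ± 32.4 FPKM (log2 -2.23, SE 0.159, adjusted p = 5.31e-06). Sdf2l1, a protein of the endoplasmic reticulum (chromosome 16, 17130138 to 17132383), fell to 4.42 ± 0.881 from 24.4 ± 3.8 FPKM (log2 -2.23, SE 0.267, adjusted p = 0.00131). Creld2 fell to 19.4 ± 1.41 from 81.9 ± 9.5 FPKM, Manf, a secreted factor induced by unfolded proteins, to 26.6 ± 3.32 from 90.8 ± 13.2, and Chac1, an enzyme that degrades glutathione, to 0.817 ± 0.206 from 6.4 ± 2.48. Higher in HS_AOS_FMT were Slc6a19 at 115 ± 36 against 49 ± 3.96 FPKM (log2 1.17, SE 0.299, adjusted p = 0.0424) and Jun at 47 ± 9.25 against 19.9 ± 4.37. Slc35f3 (log2 1.23), Afap1l2 (1.10), Akr1e1 (1.08) and Pde9a (1.03) rose too.

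The endoplasmic reticulum stress list fell in HS_AOS_FMT against HS_control_FMT, with a median log2 change of -0.71 over 26 members (adjusted p = 3.67e-17, and adjusted p = 0.0362 with an estimated correlation). Of these 11 fell and 1 rose over all genes, 14 did not pass, and 15 fell and 1 rose when adjusted over the list alone. The heat shock proteins fell (16 members, median log2 -0.89, adjusted p = 1.59e-13, and adjusted p = 0.251 with an estimated correlation). Hspb1, Hspe1, Hspa4l and Bag3 were the 4 that fell over all genes, and 11 fell when adjusted over the list alone. Hspb1 was at 52.2 ± 14.5 FPKM in HS_AOS_FMT and 195 ± 54.8 in HS_control_FMT, and Bag3, a partner of Hsp70, at 22.9 ± 5.31 and 39.3 ± 5.89. Against HS, 8 heat shock members were higher and 8 lower in HS_AOS_FMT, while 15 were higher and 1 lower in HS_control_FMT. Against control the heat shock list rose in HS_AOS_FMT by camera (adjusted p = 0.0037). That call ended without control 3 (adjusted p = 0.615), HS_AOS_FMT 3 (0.141) or the 3 adrenal-rich libraries (0.177). Markers of tubular injury fell (29 members, median log2 -0.32, adjusted p = 4.3e-05, and adjusted p = 0.871 with an estimated correlation), with Tnfrsf12a, the receptor of TWEAK, as the member that passed over all genes and over the list alone, at 31.8 ± 6.79 against 88.9 ± 14.2 FPKM. Clu, which encodes clusterin, was at 113 ± 22.6 and 189 ± 18.8 FPKM (adjusted p = 0.193). These 3 lists were called without any 1 of the 6 libraries too. The MHC class II list fell (7 members, adjusted p = 0.0353, and adjusted p = 0.871 with an estimated correlation), but it was not called without HS_control_FMT 2 (adjusted p = 0.573), HS_AOS_FMT 3 (0.0514) or after quantile normalization (0.0902). Cd74, the invariant chain, was at 1073 FPKM in HS_control_FMT 2 and at 179 and 167 in the other 2 libraries of that group. Liver markers fell as well, with 10 of 11 members lower (adjusted p = 0.00597). They were not called without HS_control_FMT 1 (adjusted p = 0.204), with the trend in GC content and length removed (0.085) or with an estimated correlation.

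In HS_AOS_FMT against HS_control_FMT 494 genes passed limma, 359 higher and 135 lower, and 2454 had an unadjusted p under 0.05. No overlap was seen for 29.3% of the genes, where chance gives 10%. Of 39 lists 9 passed, all of them down, and the endoplasmic reticulum stress list was the 1 that held with an estimated correlation. With the trend in GC content and length removed 9 passed, 3 up and 6 down, of which 6 were among those before. After quantile normalization the lists of glycolysis (adjusted p = 0.507) and antioxidant genes (0.398) were not called. The excess of higher genes shrank with the scaling: quantile normalization gave 154 higher and 129 lower, and removing the trend with GC content and length 239 higher and 217 lower. The count was 124 without HS_AOS_FMT 1, 65 without HS_AOS_FMT 2, 259 without HS_AOS_FMT 3, 150 without HS_control_FMT 1, 110 without HS_control_FMT 2 and 211 without HS_control_FMT 3. It was 218 without the 3 adrenal-rich libraries and 1143 with control 3 left out of the fit.

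**Figure D4:**
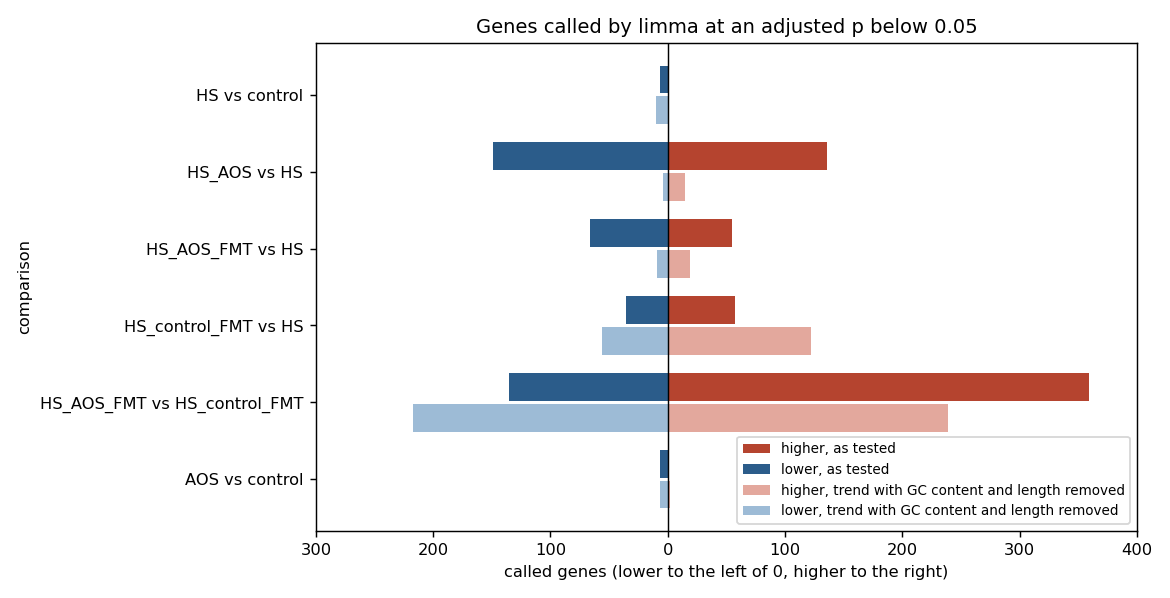
Bars give the number of genes that passed limma in each of 6 comparisons, higher to the right and lower to the left, as tested and with the trend with GC content and length removed. In HS_AOS vs HS the bars shrink from 136 higher and 149 lower to 15 and 4, and in HS_AOS_FMT vs HS_control_FMT they go from 359 and 135 to 239 and 217.

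AOS vs control asked what AOS did without the diet and STZ. Mov10, an RNA helicase that acts against viruses and retroelements (chromosome 3, 104794828 to 104818619), rose from 6.76 ± 0.244 to 10.6 ± 0.682 FPKM (log2 0.58, SE 0.0844, adjusted p = 0.00795). Without AOS 1 or AOS 3, or with the compared groups alone in the fit, 0 genes were called higher by limma, so this call ended. The other 7 genes that passed fell, and 5 of them were members of the testis list, Prm1, Prm2, Tnp1, Tnp2 and Oaz3, with the values in the controls given for the first 4 above. Oaz3 was at 2.33, 2.8 and 3.55 FPKM in controls 1, 2 and 3 and listed at 0 in the AOS libraries. The testis list fell (8 members, adjusted p = 4.23e-29, and adjusted p = 0.000151 with an estimated correlation), with 5 lower over all genes and 6 when adjusted over the list alone. Here too the filter favoured members high in the controls. Markers of intercalated cells fell as a list (15 members, median log2 -0.36, adjusted p = 0.00161, and adjusted p = 0.872 with an estimated correlation), with a median of -0.16 (adjusted p = 0.0139) without the 3 adrenal-rich libraries. With limma 0 of these passed over all genes or adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. Slc4a1, the anion exchanger of these cells, was at 5.95 ± 1.34 FPKM in AOS and 9.15 ± 2.51 in control (adjusted p = 0.674). The lists of the distal convoluted and connecting tubule (adjusted p = 0.00315), of principal cells (0.00594) and of the thick ascending limb (0.0342) also fell, with adjusted p = 0.872, 0.874 and 0.874 with an estimated correlation. Without the 3 adrenal-rich libraries their adjusted p was 0.0308, 0.0754 and 0.0803. Without control 3 the lists of principal cells and of the thick ascending limb were not called (both adjusted p = 0.0814), nor was the latter without AOS 3 (0.16) or control 2 (0.122). Markers of T, NK and B cells rose, with 10 of 12 members higher (adjusted p = 0.01). They were not called without AOS 1 (adjusted p = 0.0541), control 3 (0.323) or with an estimated correlation. Tubular injury markers fell (29 members, median log2 -0.54, adjusted p = 0.00161, and adjusted p = 0.874 with an estimated correlation), though not without control 3 (adjusted p = 0.171). Spp1, which encodes osteopontin, was at 2434 FPKM in control 3 and at 307 and 604 in controls 1 and 2, against 296 ± 26 in AOS.

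In AOS vs control 8 genes passed limma, 1 higher and 7 lower, and 902 had an unadjusted p under 0.05. Between AOS and control 13.1% of the genes had no overlap, where chance gives 10%. The median log2 change of all genes was -0.09 and after quantile normalization 0.01, so changes here are relative to that shift of 0.10. Of 39 lists 13 passed, 4 up and 9 down, the testis list held with an estimated correlation, and 6 passed without control 3, 3 of them among the 13. With the trend in GC content and length removed 16 passed, 0 up and 16 down, of which 9 were among the 13. For proximal tubule transport the test pointed up (adjusted p = 0.0119, and adjusted p = 0.192 with an estimated correlation) while the median log2 change was -0.01 and the mean 0.05, and it did not pass after quantile normalization (adjusted p = 0.696). For the interferon response the test pointed up (adjusted p = 0.0428, and adjusted p = 0.955 with an estimated correlation) with a median of 0.00 and a mean of -0.02, and it did not pass after quantile normalization (adjusted p = 0.572). The count of genes was 0 without any 1 of the controls and 0 without the 3 adrenal-rich libraries, control 3 among them. In each of these fits germ cell genes above 1 FPKM in the controls alone missed the minimum of 3 samples. Their calls thus ended by construction.

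The effect of AOS in HS was then tested against its effect in control. Itch, a ubiquitin ligase named after its values were seen, was among the 9 genes with a difference, with a log2 value of 0.79 (SE 0.128, adjusted p = 0.03), and Hist2h2aa1, a histone H2A gene, had one of -1.34 (adjusted p = 0.03). Of the other genes 5 were Prm1, Prm2, Tnp1, Tnp2 and Oaz3 of the testis list, with their values in the controls given above. For the 33 fatty acid oxidation genes the difference pointed up (median log2 0.46, adjusted p = 0.00375, and adjusted p = 0.951 with an estimated correlation), and it did not pass without HS 2 (adjusted p = 0.0881) or HS_AOS 1 (0.0685). For the 16 heat shock proteins it pointed down (median log2 -0.57, adjusted p = 5.99e-06, and adjusted p = 0.951 with an estimated correlation), and it did not pass without the 3 adrenal-rich libraries (median -0.24, adjusted p = 0.0923). By limma 0 members of either list passed over all genes, and 1 of each passed when adjusted over the list alone. The 9 genes, 8 higher and 1 lower, stand beside 1856 at an unadjusted p under 0.05. The count was 1 without control 1, 0 without control 2 or control 3, 51 without HS 1, 73 without HS_AOS 1 and 0 without the 3 adrenal-rich libraries. Wherever a control was left out, control 3 being 1 of the adrenal-rich libraries, germ cell genes above 1 FPKM in the controls alone were not tested.

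The effects of AOS, of the transfer labelled AOS and of the transfer labelled control, all measured against the same 3 HS samples, were then overlaid. Ppara, Tnfrsf21, Mtss1 and Rora rose in all 3, where Mtss1 and Rora were named after their values were seen. Ppara was at 11.8 ± 1.63 FPKM in HS, 21.5 ± 4.02 in HS_AOS, 19.5 ± 0.798 in HS_AOS_FMT and 20.8 ± 3.4 in HS_control_FMT. Hmox1 fell in HS_AOS and HS_AOS_FMT and rose in HS_control_FMT, at 38 ± 9.2, 33.4 ± 2.46 and 162 ± 32.4 FPKM against 59.8 ± 5.95 in HS. HS_AOS and HS_AOS_FMT shared 72 called genes, 35 up and 37 down, among them Hlf, Fnip2, Zkscan7 and Nat2 up and Bcl7c, Palm3 and Banp down. Independent draws would share 0.604 up and 0.794 down, and 100 simulations with the shared HS samples and no effect gave a mean of 0.03 and at most 3. With no effect in any group few genes are called, so simulated counts near 0 were nearly fixed in advance, for every pair. They do not measure what the shared HS samples add to real effects. Across genes the fold changes of HS_AOS and HS_AOS_FMT correlated at 0.573 (0.47 ± 0.212 in the simulations), with a covariance of 0.0463 (0.0232 ± 0.0157). HS_control_FMT shared 5 called genes with each, against a simulated mean of 0.01 with HS_AOS and 0 with HS_AOS_FMT, and 0.626 up and 0.433 down or 0.253 up and 0.192 down for independent draws. Its correlations were 0.212 and 0.472 (0.469 and 0.489 in the simulations) and its covariances 0.018 and 0.0369 (0.0247 and 0.0239). The 72 became 0 without HS 2 or HS 3 and 9 with the trend in GC content and length removed. The 5 shared with HS_AOS became 1 without HS 1 and 0 without HS 2 or HS 3, and the 5 shared with HS_AOS_FMT became 0 without any 1 of the HS libraries. With groups of 3 the HS samples could not be split between the comparisons, so part or all of the sharing may come from these samples. The clock score, the mean log2 of genes that peak together minus that of the opposite phase, also parted HS from these 3 groups. It was -0.0995 ± 0.174 in HS, 2.47 ± 1.29 in HS_AOS, 2.77 ± 0.349 in HS_AOS_FMT and 1.84 ± 0.526 in HS_control_FMT. In control it was 0.281 ± 2.14 and in AOS 0.599 ± 0.608, so HS was not apart from those. Hlf belongs to the clock list. Whether a difference in clock phase between HS and the treated groups gave part of the shared calls was not tested.

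Whether the treatments turned back what HS had changed was asked of the 8 genes called in HS vs control. By limma 0 of these were called in the opposite direction in HS_AOS, HS_AOS_FMT or HS_control_FMT against HS, where unadjusted counts over all genes were 2511, 2241 and 1882. Independent draws would give 0.012 up and 0.0769 down, 0.00533 and 0.0311, and 0.00291 and 0.0322, and 5 of the 8 genes were the germ cell transcripts listed at or near 0 outside the control libraries, so the 0 is no evidence against a return. Without HS 1 there was 1 such gene in HS_AOS and 1 in HS_AOS_FMT, and without control 3 there was 1 in HS_AOS. Across genes the fold change in HS vs control correlated with that in HS_AOS vs HS at -0.31, in HS_AOS_FMT vs HS at -0.35 and in HS_control_FMT vs HS at -0.20. The shared HS samples alone gave -0.51, -0.48 and -0.49 in the simulations. The covariances were -0.0214, -0.0222 and -0.0135, and -0.0266, -0.0238 and -0.0255 in the simulations.

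Against control, the stress genes of HS_control_FMT stood out again. Hmox1 was at 162 ± 32.4 FPKM in HS_control_FMT and 37.2 ± 3.05 in control (log2 2.08, adjusted p = 2.42e-06), Creld2 at 81.9 ± 9.5 and 23.4 ± 8.72, and Hspb1 at 195 ± 54.8 and 29.2 ± 12. The heat shock list rose, with 11 of 16 members higher over all genes, 14 when adjusted over the list alone, and a median log2 change of 1.17 (adjusted p = 3.45e-21, and adjusted p = 0.0397 with an estimated correlation). The endoplasmic reticulum stress list rose, with 11 of 26 members higher over all genes and 15 when adjusted over the list alone (adjusted p = 3.12e-18, and adjusted p = 0.0153 with an estimated correlation). Among other lists, immediate early genes (adjusted p = 9.28e-08) and adipose markers (0.00676) rose. Markers of intercalated cells (0.00093) and the distal convoluted and connecting tubule (0.00142) fell. So did those of principal cells (0.0172), macrophages (0.0232) and the thick ascending limb (0.0337). With an estimated correlation these had adjusted p = 0.709 or 0.838. Without control 3 the adipose, principal cell, macrophage and thick ascending limb lists were not called. In HS_AOS against control Egf fell from 284 ± 37.6 to 174 ± 3.01 FPKM and Umod from 874 ± 171 to 326 ± 94.4, both with an adjusted p of 0.0256. Counts by limma were 356 for HS_AOS, 57 for HS_AOS_FMT and 405 for HS_control_FMT, with 2268, 1913 and 2369 at an unadjusted p under 0.05. The groups did not overlap for 15.2%, 17.9% and 18.6% of the genes, where chance gives 10%. The count for HS_AOS was 84, 202 and 878 without controls 1, 2 and 3, 141 without HS_AOS 2 and 82 without HS_AOS 3. For HS_AOS_FMT it was 0, 92 and 385 without controls 1, 2 and 3, and 17, 9 and 7 without HS_AOS_FMT 1, 2 and 3. For HS_control_FMT it was 177, 175 and 213 without HS_control_FMT 1, 2 and 3.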

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

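The tests of GC content and length, of germ cell transcripts of the kidney itself and of handling before freezing were chosen only after the result was seen.

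The effect of AOS differed between HS and control, by a test of the difference itself, for 9 genes. The log2 values of the difference were 3.56 for Prm1, 2.77 for Prm2, 3.23 for Tnp2, 2.47 for Tnp1, 2.04 for Oaz3, 1.28 for Ldhc, 0.79 for Itch, -1.34 for Hist2h2aa1 and 1.53 for Gm3448. Where genes are listed at 0 in whole groups, as the first 5 are in AOS and HS, these values depend on the pseudocount and are no bound. Ldhc, Itch and Gm3448 were named after their values were seen. Of 100 random splits of the 12 samples, the real one included, 3 gave as many genes, a share under 0.05, and the highest other split gave 636. These splits also part the 3 controls that share the germ cell transcripts, so they test more than the difference of the AOS effects. The share therefore does not settle whether that difference arose by chance, and what gave the 636 was not tested.

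Germ cell transcripts in the control libraries gave most of these genes, and testis RNA in those libraries is a candidate explanation. In a second list of germ cell genes, written before its values were seen, 17 of the 30 genes with any value above 0.1 FPKM (56.7%) were higher in all 3 controls than in all 15 other libraries, where chance gives 0.123% per gene. Crisp2 was at 1, 0.66 and 1.65 FPKM in controls 1, 2 and 3 and Gsg1 at 1.2, 0.8 and 1.53, while Insl6 was at similar levels in every group. A trend with GC content or length was argued against, since 5 members of the testis list still passed in HS vs control with it removed. Germ cell transcripts of the kidney itself, lowered in every treated group, stay open, since the highest mean log2 of the testis list among the 15 other libraries was 1.31 and the lowest among the controls 2.85, which both explanations predict.

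Genes called in HS_AOS vs HS and in HS_AOS_FMT vs HS parted by GC content and length, with rank correlations between fold change and GC content of -0.465 and -0.4 across genes, and a bias in the libraries may be behind part of the calls. With the trend removed 11 of 134 raised and 3 of 147 lowered genes were still called in HS_AOS vs HS, and 11 of 53 and 5 of 66 in HS_AOS_FMT vs HS, where 19 and 28 genes were called in all, though every fold had the same sign: in HS_AOS vs HS the median of the genes that rose went from 0.441 (SD 0.133) to 0.358 (0.159) and of those that fell from -0.498 (0.308) to -0.33 (0.326), and in HS_AOS_FMT vs HS from 0.566 (0.289) to 0.464 (0.335) and from -0.478 (0.227) to -0.305 (0.279). What ended the calls was not tested, and the median standard errors were 0.0959 and 0.0967, 0.106 and 0.117, 0.11 and 0.107, and 0.0948 and 0.112, before and after in the same order. A single library was argued against as the whole cause, since the correlation closest to 0 with 1 library left out was -0.28 (without HS_AOS 3) and -0.324 (without HS_AOS_FMT 3). A real change that follows GC content and length in the treated groups was not tested and stays open.

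Endoplasmic reticulum stress and heat shock transcripts were higher in HS_control_FMT than in HS_AOS_FMT. A trend with GC content or length was argued against, since 16 members of the 2 lists passed with the trend removed and 15 before, and the medians went from -0.706 to -0.747 and from -0.891 to -0.991. Time of collection cannot be told apart from the transfer: the clock scores were 1.84 ± 0.526 in HS_control_FMT, 2.77 ± 0.349 in HS_AOS_FMT and -0.0995 ± 0.174 in HS, and the difference between the transfers was 0.48 of that between HS_control_FMT and HS, between the bounds set for either answer. Handling of the tissue before freezing cannot be told apart either: the immediate early genes had a median log2 change of -0.0383 in HS_control_FMT over HS_AOS_FMT, but 9 of 21 were higher and their SD was 0.672, so the median decides nothing. An effect of the transfer stays open as the biological explanation.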

How the results depend on the processing

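Removing the trend with GC content and length, leaving out the 3 adrenal-rich libraries and leaving control 3 out of the fit were chosen only after the data were seen.

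Of the named genes, 102 results passed in their comparison and 102 kept their direction under every alternative that gave a value. Most were named for large changes and values that did not overlap, so a kept direction was nearly fixed by that choice. With array weights, which leaned on single libraries in some groups as given below, 102 also passed. With a pseudocount of 0.1 95 passed, after quantile normalization 92, without the trend option of limma 83, with the GC and length trend removed 67, with no filter 61 and with the compared groups alone in the fit 50. Without the 3 adrenal-rich libraries 35 passed, 57 did not and the rest had no value, and with the replicate number as a block 67 passed and 35 did not. With each library left out in turn, pairs of a result and a left-out library were counted. Of the pairs with a value 254 passed and 328 did not.

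The counts of called genes below are those that moved by more than 1.5 times, and except where stated the cause was not tested. With array weights they were 104 in HS vs control, 4084 in HS_AOS vs HS, 1711 in HS_AOS_FMT vs HS, 1473 in HS_control_FMT vs HS, 2409 in HS_AOS_FMT vs HS_control_FMT, 13 in AOS vs control, 1914 for the difference of the AOS effects, and 3420, 1148 and 1976 for HS_AOS, HS_AOS_FMT and HS_control_FMT vs control. The weight was 5.8 for HS_AOS 2 against 0.366 and 0.407 for HS_AOS 1 and 3. It was 3.85 for HS_control_FMT 1 against 0.811 and 0.37 for HS_control_FMT 2 and 3. The weighted means of these groups thus rest mostly on 1 library each.

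With no filter the counts were 245 in HS vs control, 130 in HS_AOS vs HS, 43 in HS_AOS_FMT vs HS, 46 in HS_control_FMT vs HS, 233 in AOS vs control, 184 for the difference of the AOS effects, and 661, 431 and 724 for HS_AOS, HS_AOS_FMT and HS_control_FMT vs control. In HS vs control 12 of them were higher and 233 lower, and in AOS vs control 7 were higher and 226 lower. How many of the lower ones were germ cell transcripts of the controls was not counted. With at least 5 FPKM in 3 samples they were 1 in HS vs control, 202 in HS_AOS_FMT vs HS, 3 in AOS vs control and 0 by limma for the difference of the AOS effects (1856 genes at an unadjusted p under 0.05 with the filter of 1 FPKM). Prm2, Tnp1 and Oaz3 then miss the filter by construction, and Tnp2 had an adjusted p of 0.0614 in HS vs control and 0.041 in AOS vs control.

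With the compared groups alone in the fit, which leaves fewer samples to estimate the spread, the counts were 5 in HS vs control, 1 in HS_AOS vs HS, 25 in HS_control_FMT vs HS, 215 in HS_AOS_FMT vs HS_control_FMT, 5 in AOS vs control, and 6, 6 and 10 for HS_AOS, HS_AOS_FMT and HS_control_FMT vs control. Requiring a log2 fold change of at least 1 gave, by construction fewer, 9 in HS_AOS vs HS, 6 in HS_AOS_FMT vs HS, 19 in HS_control_FMT vs HS, 40 in HS_AOS_FMT vs HS_control_FMT, and 49, 11 and 94 for HS_AOS, HS_AOS_FMT and HS_control_FMT vs control.

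After quantile normalization the counts were 477 in HS_AOS vs HS, 283 in HS_AOS_FMT vs HS_control_FMT and 141 in HS_AOS_FMT vs control. Without the trend option of limma they were 185 in HS_AOS vs HS, 41 in HS_AOS_FMT vs HS and 37 in HS_AOS_FMT vs control. With the GC and length trend removed they were 19 in HS_AOS vs HS, 28 in HS_AOS_FMT vs HS, 178 in HS_control_FMT vs HS, and 179, 30 and 667 for HS_AOS, HS_AOS_FMT and HS_control_FMT vs control.

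Without the 3 adrenal-rich libraries the counts by limma were 4 in HS vs control (0 of them among the 8 called before), 0 in HS_AOS vs HS, 1 in HS_AOS_FMT vs HS, 218 in HS_AOS_FMT vs HS_control_FMT, 0 in AOS vs control, 0 for the difference of the AOS effects and 618 in HS_AOS vs control, where those at 0 had 2511, 902 and 1856 genes at an unadjusted p under 0.05 with all libraries. Control 3 is among these libraries, so germ cell genes above 1 FPKM in the controls alone then missed the filter and were not tested. With control 3 left out of the fit the counts were 828 in HS_AOS vs HS, 619 in HS_AOS_FMT vs HS, 350 in HS_control_FMT vs HS and 1143 in HS_AOS_FMT vs HS_control_FMT, and all 285, 121, 93 and 494 genes called before were among them.

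The replicate numbers gave little sign of a pairing: of 45 pairs of libraries with the same number 14 had residuals that correlated above 0.1, the range was -0.356 to 0.312, and 7 of 18 libraries were closest to their own number. Control and HS were the 1 of 15 pairs of groups where every such correlation was above 0.1 (0.188, 0.243 and 0.121), so a pairing of these 2 is not excluded, and with the number as a block HS vs control had 0 genes higher and 7 lower, without Gm20594. With the block the other counts were 89 in HS_AOS vs HS, 37 in HS_AOS_FMT vs HS, 276 in HS_AOS_FMT vs HS_control_FMT, 196 in HS_AOS vs control and 16 in HS_AOS_FMT vs control. Shared genes were then 19 for HS_AOS and HS_AOS_FMT, 2 for HS_AOS and HS_control_FMT and 1 for HS_AOS_FMT and HS_control_FMT, and with the GC and length trend removed 9 and 1 for the first 2 pairs.

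Of the lists that passed, an estimated correlation left 1 in HS vs control, 0 in HS_AOS vs HS, 0 in HS_AOS_FMT vs HS, 1 in HS_control_FMT vs HS, 1 in HS_AOS_FMT vs HS_control_FMT and 1 in AOS vs control. Among all lists 1, 1, 0, 1, 3 and 1 passed by fry in the same order, and of the 3 between the transfers 2 had passed before.

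With 1 library left out the counts of genes went from 0 to 8 in HS vs control, 0 to 789 in HS_AOS vs HS, 0 to 93 in HS_AOS_FMT vs HS, 16 to 45 in HS_control_FMT vs HS, 65 to 259 in HS_AOS_FMT vs HS_control_FMT, 0 to 8 in AOS vs control and 0 to 73 for the difference of the AOS effects. They went from 82 to 878, 0 to 385 and 175 to 538 for HS_AOS, HS_AOS_FMT and HS_control_FMT vs control. Wherever a control was left out, germ cell genes above 1 FPKM in the controls alone missed the filter and were not tested. The lowest and highest came without control 1 and HS 3 in HS vs control, HS 2 and HS_AOS 1 in HS_AOS vs HS, HS 3 and HS 1 in HS_AOS_FMT vs HS, HS 1 and HS_control_FMT 3 in HS_control_FMT vs HS, HS_AOS_FMT 2 and HS_AOS_FMT 3 between the transfers, and control 1 and AOS 1 in AOS vs control. The lists that passed went from 9 to 18, 1 to 12, 9 to 15, 9 to 14, 9 to 13 and 6 to 15 in the 6 main comparisons in the order used above. Genes of HS vs control called in the opposite direction went from 0 to 1 in HS_AOS, 0 to 1 in HS_AOS_FMT and 0 to 0 in HS_control_FMT, and shared genes from 0 to 83, 0 to 1 and 0 to 0 for the pairs above.

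The depth of the libraries is known only as a rough estimate, and with 3 samples per group the test on simulated data recovered 93% of genes changed by 2-fold. That share is for genes with a mean log2 level of at least 2 and noise independent between genes. It is therefore no measure of the power in these libraries.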

Other observations

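The splits of the samples reported in this part were planned, and the genes in its first paragraphs were chosen after their values were seen.

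Brown fat transcripts varied between libraries of the same group. Ucp1, which uncouples respiration in brown fat, was at 42.5 FPKM in HS 3, 129 in HS_AOS_FMT 2, 67.2 in HS_AOS_FMT 3 and 133 in HS_control_FMT 1, and at 19 or less in the other 14 libraries. Cidea, a lipid droplet gene of the same tissue, was at 43.5, 45.5, 29.1 and 65.9 FPKM in those 4. Genes of the adrenal cortex were high in 3 of them: Star, which brings cholesterol into mitochondria, was at 46.6, 53.3 and 9.74 FPKM in HS 3, HS_AOS_FMT 2 and HS_AOS_FMT 3 and at 0.71 in HS_control_FMT 1.

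The beta globin Hbb-bs was at 0 FPKM in control 1, 0.58 in HS_AOS 1, 1.04 in AOS 1, 2.93 in AOS 2 and 6.51 in HS_control_FMT 1, and between 42.4 and 2593 in the other 13 libraries. The alpha globin Hba-a1 did not follow it, at 5388 FPKM in control 1, 4655 in HS_AOS 1 and 6892 in AOS 1. Genes of antigen presentation were high in HS_control_FMT 2, where Cd74 was at 1073 FPKM and H2-Ab1, an MHC class II chain, at 489, against 660 and 246 in control 3 and less in all others. Pck1, the rate-limiting enzyme of gluconeogenesis, was at 2395 FPKM in HS 1 and at 775 and 799 in HS 2 and HS 3, and Cyp4a14, a target of PPAR alpha, at 68.8, 6.25 and 6.41 in the same libraries.

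Clock scores, the mean log2 of genes that peak together minus that of genes in the opposite phase, were 0.281 ± 2.14 in control, 0.599 ± 0.608 in AOS, -0.0995 ± 0.174 in HS, 2.47 ± 1.29 in HS_AOS, 2.77 ± 0.349 in HS_AOS_FMT and 1.84 ± 0.526 in HS_control_FMT. Dbp, an output gene of the clock, was at 2.76 and 6.9 FPKM in controls 1 and 2 and at 90.6 in control 3.

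Each comparison of 3 against 3 samples has 10 splits, too few for a share under 0.05. The real split alone gave as many called genes (1 of 10) in HS vs control (8, highest other 7), HS_AOS vs HS (285, highest other 3), HS_AOS_FMT vs HS (121, highest other 0), HS_control_FMT vs HS (93, highest other 0), HS_AOS_FMT vs HS_control_FMT (494, highest other 1), AOS vs control (8, highest other 0) and HS_AOS_FMT vs control (57, highest other 0). In 2 of 10 splits there were as many in HS_AOS vs control (356, highest other 501, controls 1 and 2 with HS_AOS 3) and in HS_control_FMT vs control (405, highest other 612, controls 1 and 2 with HS_control_FMT 3). Both of these put control 3 on the other side.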
